A study of Mus musculus with 4 samples.

How the data were processed

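Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of SOX3, a transcription factor of the SOX B1 group, was analysed from mouse testis at postnatal day 7. The labels give 3 SOX3 ChIP samples with replicate numbers and 1 input sample, the chromatin before immunoprecipitation. The series' design text says that the ChIP samples came from 3 different testes and were compared with input DNA. Whether the testes came from different animals is not given in the sources used here, so the replicates measure the spread between testes. The labels' protocols describe a Sox3 null line bred onto the 129/SvJ background and give no genotype for the single testes.

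Per the labels' protocols, testes were fixed in 1% formaldehyde for 8 min, sonicated for 15 min and immunoprecipitated with a goat antibody against human SOX3, and libraries were sequenced as 50 bp single reads. Bowtie2 2.0.0 and genome build mm9 are named per the submitters' processing notes. The peak names in the deposited lists begin with MACS. The version and settings of the peak caller, the treatment of reads that map to several places and the removal of duplicate reads are not given in the sources used here. These steps could change the peaks in repeated sequence, where 1 read fits several places.

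Each ChIP sample has 1 deposited peak list, called per sample, with the position of each peak and the authors' score. The score is the authors' own value per peak. Its minimum lay at 40 in every list, as minus 10 times log10(p) with a limit of 0.0001 would give, but no source used here names its scale. It was used only to describe, rank or filter peaks within a list. A further deposited table holds the peaks common to the replicates, 1 for the whole group, annotated with HOMER's annotatePeaks.pl on mm9, per the file headers. The header names a peak file of sites found in at least 2 samples. The deposited distance to the transcription start site (TSS), in bp and negative upstream, the class of each site and the repeat it lies in are HOMER's, per the file headers. The deposited peak score of the common table was 0 in all 778 rows and was not used.

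The number of reads per library is unknown, since peak lists hold no read numbers. Precision was therefore judged from the number of peaks, and shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only. The input sample was not analysed here, so no value carries a background measured in it.

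Peaks of different lists were counted as shared when they overlapped by at least 1 bp, and the counts were checked with bedtools 2.31.1. The observed overlap was set against 1000 circular shifts of 1 list within its chromosomes (one-sided permutation test, Benjamini-Hochberg adjusted over the directed pairs). The smallest p that 1000 shifts can give is 0.000999. Scores of peaks shared by all 3 replicates and of peaks in a single list were compared within each list by a permutation test of the difference in medians (two-sided, 100000 resamples). A common peak was assigned to a replicate list when it overlapped one of its peaks by at least 1 bp, and took the score of that peak.

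A gene counted as bound when HOMER named it as the nearest gene of a common peak and the TSS distance was within 5000 bp. The background was the 21900 protein-coding genes of the RefSeq table for assembly GRCm38.p6, which was used for gene names, gene types and neighbourhood only, so that no coordinate of that assembly is printed. Of the 778 common peaks, 776 had a nearest gene whose identifier was in that table. The 34 gene lists, of cell type markers, pathways, complexes and gene families, were written down with the groups, the tests and the alternatives before the data were examined. The histone list and the 15 genes reported in every case were chosen with general knowledge of published work on SOX3, so they are not independent of it. Each list was tested by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the 34 lists, threshold 0.05). List members were matched on current symbols and synonyms. Of the bound genes, synonyms brought in Ubb among the ribosomal protein genes, Sf1, Tnrc18 and Zmym2 among the Zfp genes and Hist1h2br among the histone genes. Common peaks per chromosome were compared with the share of annotated genes by exact binomial tests (two-sided, Benjamini-Hochberg adjusted over 21 chromosomes), since chromosome lengths of mm9 were not used here.

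The genes named follow a rule: the nearest genes of the 10 common peaks with the best mean score rank over the replicate lists, since the common table's own score was 0; up to 4 members with the smallest TSS distance of each list with a bound gene; the 15 genes fixed in advance; and the genes of any region of 50 kb or less with at least 4 common peaks. Genes named outside this rule are said to be so. Comparisons of repeat and promoter classes between peaks in 2 and in 3 lists (Fisher's exact test, two-sided, adjusted over 8 classes), of histone peaks with other peaks near a TSS, and of single chromosomes without 1 kind of peak were added after the data were seen. So was a permutation test (one-sided, 100000 resamples) that placed runs of as many neighbouring protein-coding genes as the histone loci hold at random in the gene order, outside the histone genes.

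The code was tested on simulated data. With 0, 5 and 15% of 2912 peaks planted as shared, mean recovered shares were 0.046, 5.06 and 15.05%, and 3, 100 and 100 of 100 simulations gave a call. With 0, 5 and 20 bound histone genes planted among 21900 genes, the histone list was called in 0, 50 and 50 of 50 simulations, while 1, 0 and 5 of 1650 tests of the other lists gave a call.

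Alternatives covered the overlap rule (50% reciprocal overlap, midpoints within 100 bp, a gap of up to 500 bp), peaks at or above each list's median score, autosomes and X only, uniform random placement, peaks found in all 3 lists, TSS windows of 500, 1000 and 5000 bp or any distance, all annotated genes as background, neighbouring genes within 500 kb as 1 locus (a locus counts as bound if any member is, while the background stays single genes, so this setting favours clustered lists), peaks within 10 kb counted as 1, expected numbers from protein-coding genes, and each replicate left out. Leaving out common peaks in satellite, rRNA and snRNA repeats and matching on current symbols alone were added after the data were seen, as were leaving out 3 LTR families with repeated scores and counting as 1 the peaks of a class that lay within 50 kb, without or together with peaks of repeated scores (equal scores in every list, or 1 repeat name and an equal score in a list). The planned motif search and the comparison of TSS distance with random positions need the mm9 sequence and annotation, which were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.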

Results

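SOX3 binding was profiled by ChIP-seq in mouse testis at postnatal day 7, an age at which the seminiferous tubules hold spermatogonia and somatic cells and no haploid germ cells. The data were the authors' peak lists of 3 SOX3 ChIP samples and their annotated table of 778 peaks common to the replicates, in mm9 coordinates. A single input sample served as the background, per the design text, and no values of it were analysed here. The lists held 2912, 2598 and 2734 peaks in replicates 1, 2 and 3, a mean of 2748 ± 158 (SD, n = 3). Median peak widths were 165, 164 and 153 bp. The authors' score had medians of 47.8, 48.1 and 47.3 and maxima of 2899.6, 2081 and 2162, and a score of 100 or more was reached by 223, 203 and 196 peaks. The read depth of the libraries is unknown.

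The strongest SOX3 peaks were found in every testis, and most weak peaks in a single one. The 4 peaks of highest score in each list lay at the same places, within an intron of Tex14, a gene needed for the intercellular bridges of germ cells. All 20 common peaks with the best mean rank were present in all 3 lists. Among these 20, 10 lay in small nuclear RNA (snRNA) repeats and 4 at promoters.

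Between pairs of replicates, 402 to 459 peaks were shared, which was 15.04 to 16.8% of a list. Of the peaks of replicate 1, 438 (15.04%, 95% interval 13.8 to 16.4%) overlapped a peak of replicate 2 and 443 (15.2%, 13.9 to 16.6%) one of replicate 3. Randomly shifted lists shared a mean of 1.24 to 1.47 peaks. The observed overlap was 298 to 335 times as large in the 6 directed comparisons (adjusted exact permutation p = 0.000999 for each, the smallest that 1000 shifts can give). Peaks of replicate 1 that overlapped both other lists numbered 241 (8.28%, 7.30 to 9.34%), against a mean of 0.003 in shifted lists (permutation p = 0.000999, the smallest possible). In contrast, 78.0, 77.1 and 77.2% of the peaks of replicates 1, 2 and 3 were in no other list. Under a 50% reciprocal overlap the number shared by all 3 was 157.

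Strong peaks were shared more often than weak ones in each list. Of peaks with a score from 40 to below 50, 10.4, 12.6 and 10.7% were found in another list, and 16.8, 12.3 and 19.2% at 50 to below 60. The shares were 40.2, 41.4 and 46.98% at 60 to below 100, and of peaks with a score of 100 or more, 83.4% (77.9 to 88.04%), 85.7% (80.1 to 90.2%) and 87.2% (81.8 to 91.6%). Peaks shared by all 3 replicates had a median score of 115 against 46.2 for peaks of a single list in replicate 1, 111 against 46.4 in replicate 2 and 108 against 46.04 in replicate 3. The difference held in 3 of 3 lists (permutation p = 1e-05 in each, the smallest that 100000 resamples can give).

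**Figure D1:**
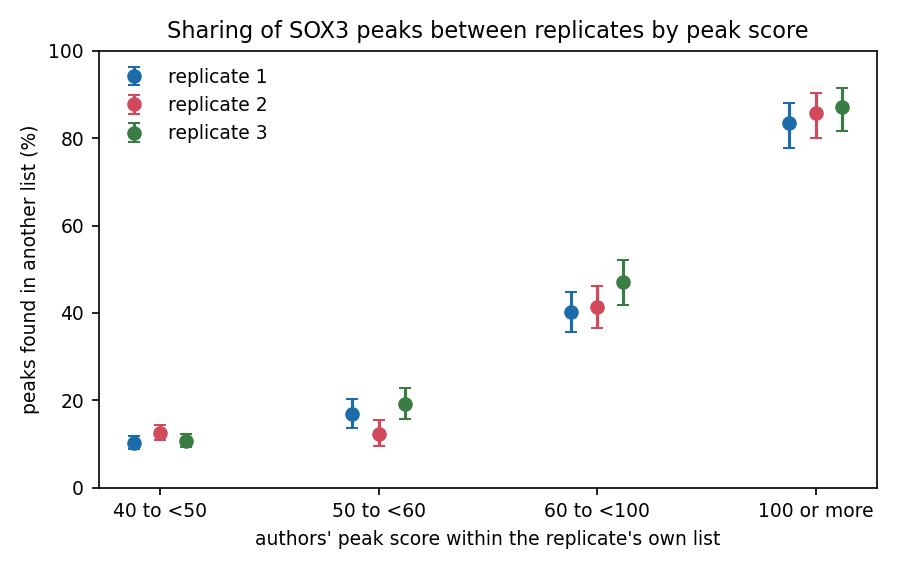
Share of peaks of each replicate list that overlapped a peak of another list (vertical axis, percent) by the authors' score (horizontal axis, 4 ranges). Points are the 3 replicates and bars exact 95% binomial intervals; the share lies between 10.4 and 12.6% at scores from 40 to below 50 and between 83.4 and 87.2% at 100 or more.

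The common table listed 778 peaks, and every one overlapped a peak in at least 2 replicate lists. Of these, 233 (29.95%) were in all 3 lists and 545 (70.05%) in 2. Replicate 1 lacked 158, replicate 2 lacked 202 and replicate 3 lacked 185 of them. The common peaks had a median width of 280 bp. With a 50% reciprocal overlap, 155 were in all 3 lists.

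SOX3 common peaks lay mostly away from promoters, but peaks at promoters and at histone genes were found in all 3 testes more often than the rest. By HOMER's classes, 386 (49.6%) were intergenic, 241 (30.98%) intronic, 85 (10.9%, 8.82 to 13.3%) at promoters and 25 exonic. Of the promoter peaks 44 (51.8%) were in all 3 lists, against 27.3% of the other common peaks (Fisher's exact test, adjusted exact p = 1.33e-05). Of the 38 common peaks at replication-dependent histone genes 23 (60.5%) were in all 3 lists, against 28.4% of the rest (adjusted exact p = 0.000101). Among peaks in all 3 lists the promoter share was 18.9%.

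Repeated sequence held 303 of the common peaks (38.95%), and its classes differed in how often peaks recurred. Sequences of snRNA, the RNA components of the spliceosome and their relatives, held 36 peaks, of which 30 (83.3%) were in all 3 lists (adjusted exact p = 1.16e-10 against the other common peaks). With peaks within 50 kb or of repeated scores counted as 1, 15 of 18 snRNA units were in all 3 lists (adjusted exact p = 1.065e-05). LINE L1 retrotransposons held 96 peaks, and 4 of them (4.17%) were in all 3 lists, against 33.6% of the others (adjusted exact p = 1.16e-10). LTR retrotransposons held 74 peaks with 3 (4.05%) in all 3 lists (adjusted exact p = 2.51e-08). Some retrotransposon peaks carried repeated scores, and with peaks of repeated scores or within 50 kb counted as 1, 4 of 75 LINE L1 units (adjusted exact p = 4.18e-07) and 3 of 51 LTR units (adjusted exact p = 3.87e-05) were in all 3 lists. Satellite repeats held 21 peaks, 1 of them in all 3 lists, and 20 of the 21 were absent from replicate 2. These peaks lay in 4 regions of peaks within 50 kb of each other, of which 1 held a peak in all 3 lists, against 28.3% of other regions (adjusted exact p = 1). Of the 14 peaks in rRNA repeats, 4 (28.6%) were in all 3 lists, which was not told apart from the other peaks (adjusted exact p = 1). The best score over the lists had a median of 207 for snRNA repeats, 70.5 for satellites, 62.2 for LTRs and 52.2 for LINEs.

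**Figure D2:**
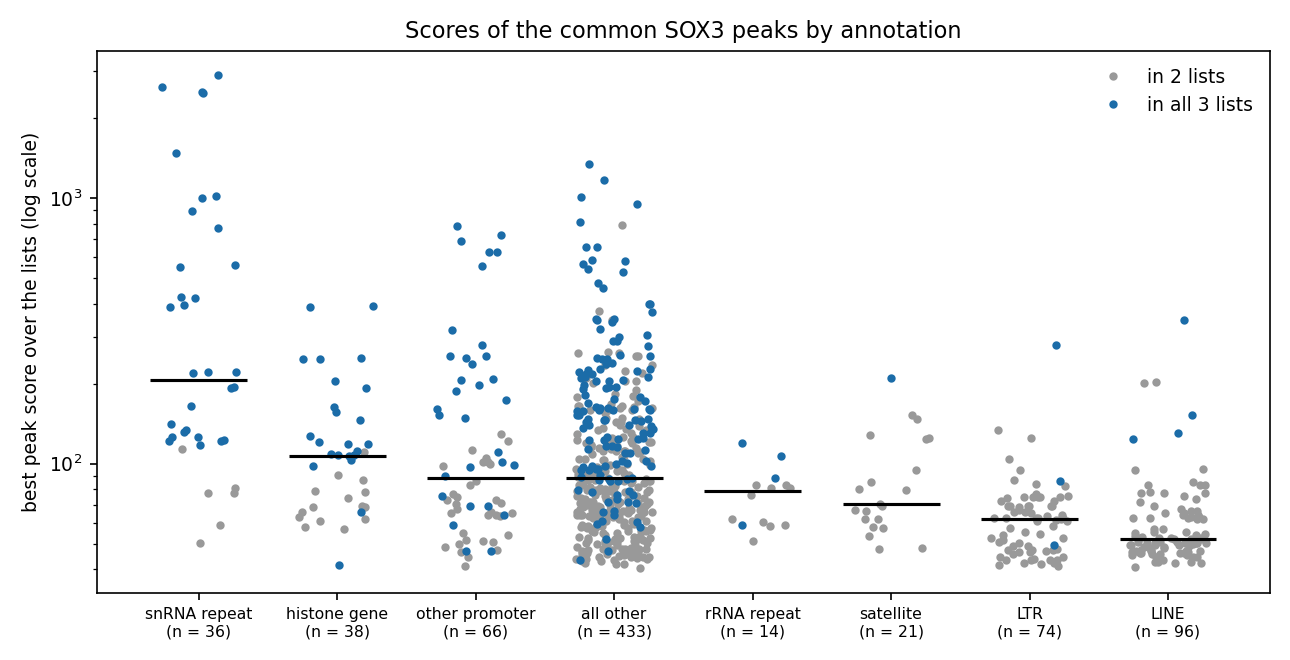
Best authors' score over the replicate lists (vertical axis, log scale) of the 778 common peaks, grouped by annotation (horizontal axis), with blue points for peaks in all 3 lists, grey points for peaks in 2 lists and black lines for medians. The snRNA repeats reach the highest scores, with a median of 207 over 36 peaks, and 30 of the 36 are blue.

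The highest scores lay at 4 U3 copies in an intron of Tex14. U3 is a small nucleolar RNA of ribosomal RNA processing that the repeat annotation lists under snRNA. The leading peak, at chromosome 11, 87275409 to 87276317, 34770 bp downstream of the TSS, had scores of 2899.6, 2081 and 2162 in replicates 1, 2 and 3. The others, starting at 87284521, 87261722 and 87256353, had scores between 1710.2 and 2614. A further peak lay at the Tex14 promoter, 683 bp upstream of the TSS, with scores of 725, 344 and 423. Next in rank came an intronic peak of 4930415F15Rik on chromosome 11, from 11397629 to 11398506, with scores of 1172, 1007 and 970.0 in replicates 1, 2 and 3.

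Peaks in U1 copies, the snRNA that recognises the 5′ splice site, followed. An intergenic U1 peak 14586 bp upstream of Eapp, a regulator of E2F, lay on chromosome 12 from 55810883 to 55811993 with scores of 1480.2, 857 and 813. A second intergenic peak near Eapp, from 55838911 to 55839950, carried no repeat and scored 1348, 841 and 706. On chromosome 3, U1 peaks from 96290120 to 96291035 and from 96292180 to 96293188 had BC107364 and Hfe2, the hemojuvelin gene of iron balance, as nearest genes, 34348 and 36424 bp from their TSSs. The scores of the former were 1018, 839.7 and 838. The last of the 10 lay in intron 1 of Nxn, a nucleoredoxin gene, on chromosome 11 from 76191173 to 76191993 with scores of 954, 798 and 790.1. Reads from near-identical snRNA copies can fit several places, and the authors' handling of them is not given in the sources used here.

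SOX3 common peaks were concentrated at replication-dependent histone genes, which encode the histones made for packaging newly replicated DNA. Of the 67 such genes, 32 (47.8%, 95% interval 35.4 to 60.3%) had a common peak within 5000 bp of the TSS, against 124 of 21833 other protein-coding genes (0.568%), a ratio of 84.1 (Fisher's exact test, adjusted exact p = 2.43e-50). By family, 9 of 13 H4 genes, 8 of 12 H3 genes, 9 of 18 H2B genes, 3 of 6 H1 genes and 3 of 18 H2A genes were bound. Each peak counted for its nearest gene alone. Both Hist1h2br peaks were classed at a promoter under the transcript name given at a Hist1h2ao peak. Both Hist2h3c2 peaks were classed at the end of the transcript named at Hist2h2aa1. The split between families, such as H2A and H2B, thus depends on this assignment and was not tested. The list was chosen with knowledge of published work on SOX3 and is not independent of it.

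The 38 histone peaks had best scores from 41.7 to 391.6, with a median of 107. The peak nearest to a TSS was at Hist1h2ao (chromosome 13, 21925148 to 21925768, 14 bp upstream; scores 112, 41.2 and 76.8). Hist2h2aa1 on chromosome 3 had the highest scores, at a pair of places to which the annotation gave 1 transcript name. The promoter peak from 96043951 to 96044533, 15 bp downstream of a TSS, scored 336, 381 and 392. That from 96049191 to 96049726, 38 bp downstream of another TSS, scored 351, 388 and 383. Near-identical copies can share reads, so these peaks may not be separate signals. Hist2h3b had a promoter peak 56 bp downstream of its TSS with scores of 109, 45.9 and 73.2. Hist1h2bc had one 72 bp downstream, with scores of 52.1 in replicate 1 and 69.02 in replicate 3 and no peak in replicate 2. On chromosome 13, 30 peaks at 27 genes lay between 21809474 and 24026204, and on chromosome 3, 8 peaks at 5 genes between 96024558 and 96072813.

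The bound histone genes lay in 3 of the 5 places where histone genes stand, with 13 of 23 and 14 of 31 genes bound on chromosome 13 and 5 of 10 on chromosome 3. Runs of as many neighbouring genes placed at random held a mean of 0.333 places with a bound gene (one-sided permutation p = 0.00137). Without replicate 1, 2 or 3, the bound histone genes numbered 24, 21 and 25, and the largest adjusted exact p was 2.06e-31. Among peaks found in all 3 lists the number was 19 (28.4%, adjusted exact p = 5.92e-30). Histone peak midpoints lay a median of 184 bp downstream of the TSS (quartiles 99.5 and 256.8 bp). The other 96 common peaks within 1000 bp of a TSS had a median of 15.5 bp (quartiles −151 and 195 bp), a difference of 169 bp (permutation p = 0.0015). That test took histone peaks as separate, although they lay in 3 places and some copies repeated their distance. The Hist1h2br peaks both lay 373 bp and the Hist2h3c2 peaks both 192 bp downstream. Its p may therefore be too small, and the distances depend on which gene was named nearest. A pair of Hist2h3c2 peaks 381 bp wide, starting at 96042668 and 96050625 on chromosome 3, had equal scores in all 3 replicates (103, 69.7 and 118). A pair of Hist1h2br peaks 337 bp wide, starting at 21901527 and 21925817 on chromosome 13, had equal scores in replicates 1 and 2 (64.9 and 81.8).

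**Figure D3:**
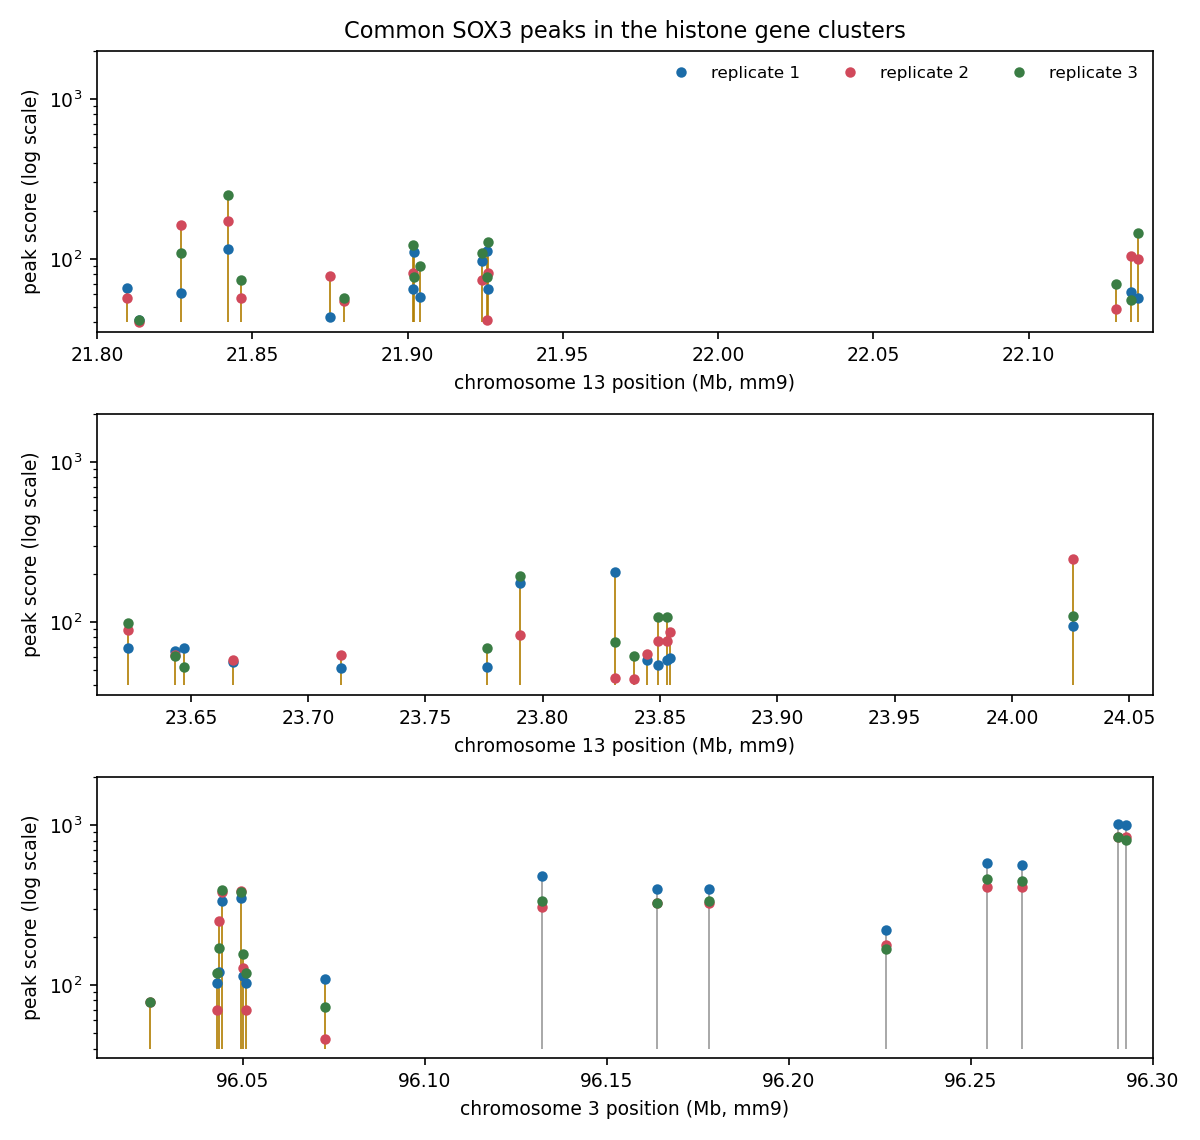
Common peaks in the histone gene clusters, with position in Mb (mm9, horizontal axes) and the authors' score in each replicate list (vertical axes, log scale) for 2 regions of chromosome 13 and 1 of chromosome 3. Points are replicates, brown lines mark peaks at histone genes and grey lines other peaks; histone scores stay at or below 391.6, while the U1 peaks at the right of chromosome 3 reach 1018.

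Other bound gene groups were few. Replication-independent histone genes had 3 of 13 members bound (23.1%, 5.04 to 53.8%, ratio 33.01, adjusted exact p = 0.00164). These were H3f3b, encoding H3.3 (99 bp downstream of the TSS; scores 137, 133 and 249.6), H2afx, encoding the damage-responsive H2A.X (37 bp downstream; 83.8, 80.3 and 110.4), and H1fx (88 bp upstream; 56.1, 90.1 and 48.9), and all 3 were in all 3 lists. Splicing and RNA-binding genes had 5 of 117 bound (4.27%, 1.40 to 9.69%; ratio 6.17; adjusted exact p = 0.0129). They were Srsf7, a splicing factor (61 bp upstream; scores 112, 116 and 255), Hnrnpk, Hnrnph1, Hnrnpa2b1 and Hnrnpu. Without replicate 3 the splicing list had 3 bound members and an adjusted exact p of 0.168, and the range over all settings was 0.000713 to 0.168.

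Olfactory receptor genes, which are silent in most tissues, had 0 of 1109 members bound (upper limit 0.332%), against 0.750% of other genes (adjusted exact p = 0.00732). The call was lost with receptor clusters counted as 55 loci (adjusted exact p = 1) and whichever replicate was left out (0.0577 to 0.0763). The list of Zfp genes had 8 of 469 bound (1.71%) and the list of other histone modifiers 2 of 31 (Brd2 and Kdm5b; 6.45%), neither past the threshold (adjusted exact p = 0.116 for both). In total 4 of the 34 lists passed, and 6 had an unadjusted exact p under 0.05.

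A further 10 lists had a single bound gene each and none passed (adjusted exact p of 0.367 or above). They included germ cell identity (Tex14, 1 of 20), Wnt signalling (Tcf7, 3486 bp upstream, 1 of 24), Polycomb and Trithorax (Kmt2a, 55 bp upstream, 1 of 27) and cell cycle (Cdc20, 221 bp upstream, 1 of 36). Neurogenic genes (Neurog3, 1 of 24), cytosolic ribosomal proteins (Ubb by a synonym, 1 of 91), the respiratory chain (Ndufaf3, 1 of 99), vomeronasal receptors (Vmn2r15, 1 of 357) and keratins (Krt76, 1 of 107) made up the rest with the progenitor list below. The SOX and Hox families and the Notch, retinoic acid, GDNF and FGF, DNA methylation, proteasome, tRNA ligase and Usp lists had 0 bound genes. Their upper limits lay between 6.98 and 26.5%, so moderate shares were not excluded. The fixed Notch list did not include Nrarp, a Notch target and feedback inhibitor with a promoter peak in all 3 lists.

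Few genes that mark testis cell types had a common peak, and few genes did overall. The single bound gene among the 10 cell type lists was Neurog3, a transcription factor of spermatogonia that leave the stem cell state, in the list of committed progenitors (1 of 11; 9.09%, 0.230 to 41.3%, against 0.708% of other genes; adjusted exact p = 0.367). Markers of stem and undifferentiated spermatogonia (0 of 25), differentiating spermatogonia (0 of 13), meiosis (0 of 31), spermatids (0 of 20), Sertoli cells (0 of 21), Leydig cells (0 of 12), peritubular myoid cells (0 of 10), endothelium (0 of 10) and macrophages (0 of 10) had none. Over the spermatogonial lists together 1 of 48 genes was bound and over the somatic lists 0 of 62 (upper limit 5.78%). A difference between these groups was not tested.

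Of the 15 genes fixed in advance, Neurog3 alone was the nearest gene of a common peak. That peak was intergenic, on chromosome 10 from 61591507 to 61591858, 4156 bp upstream of the TSS. It scored 99.3 in replicate 1 and 44.8 in replicate 3 and had no overlapping peak in replicate 2. Sox3 itself, the spermatogonial genes Kit, Gfra1, Zbtb16, Id4, Nanos2, Sohlh1, Sohlh2, Dmrt1 and Stra8, and Sox2, Sox9, Dbx1 and Hes1 were the nearest gene of 0 common peaks.

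**Figure D4:**
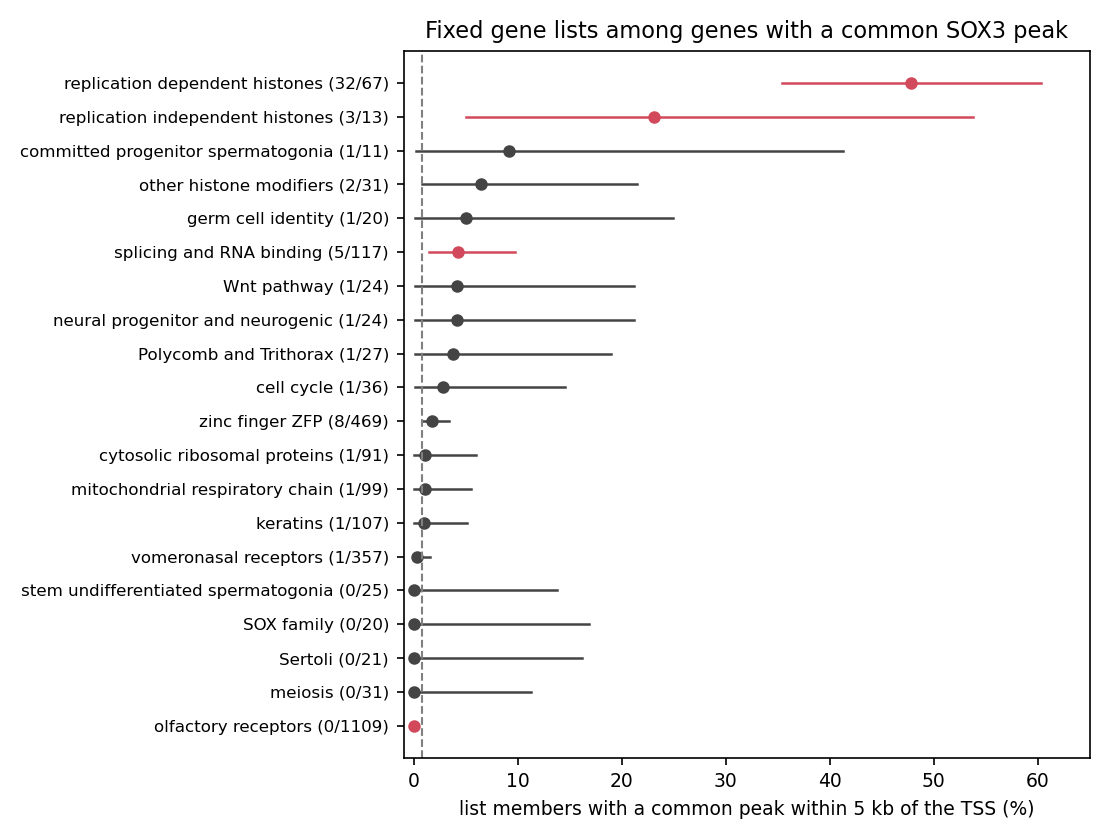
Share of the members of each fixed gene list with a common peak within 5000 bp of the TSS (horizontal axis, percent), for the lists with a bound gene and 5 lists with none, with exact 95% intervals, bound and total members in brackets and lists past the threshold in red. The dashed line is the share of other genes; the replication-dependent histones stand at 47.8%.

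Common peaks clustered at a few places. Of the 14 regions of at most 50 kb with 4 or more common peaks, holding 85 peaks, 5 were histone regions with 29 peaks. The regions with snRNA repeat peaks were those of Tex14 (5 of 6 peaks), Rdm1 and LOC666331 (3 of 4), Eapp (3 of 9) and BC107364 with Hfe2 (3 of 4). Satellite repeats made up all or most of 2 regions, at Mir101c on chromosome 9 (15 of 16 peaks) and at Lrrc4c on chromosome 2 (4 of 4 peaks). The remaining 3 were at Cox20 and Hnrnpu on chromosome 1 (5 peaks), Ypel1 and Ppil2 on chromosome 16 (4) and Phf10, Gm3448, 9030025P20Rik and Gm3417 on chromosome 17 (4).

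Chromosome 13 held 65 common peaks where 35.4 would follow from its genes (1.84 times; exact binomial test, adjusted exact p = 8.2e-05), the largest excess of the 21 chromosomes. Without the histone peaks it held 35 against 33.6 expected (adjusted exact p = 0.874). Chromosome 9 held 59 peaks (1.52 times, adjusted exact p = 0.00867), and 43 against 37.7 expected without its satellite peaks (adjusted exact p = 0.495). This call was also lost with peaks within 10 kb counted as 1 (0.593), without replicate 1 (0.794) and without replicate 3 (0.956). Chromosome 1 had 1.49 times the expected number (adjusted exact p = 0.00867), chromosome 2 had 0.572 times (0.00376) and chromosome 7 had 0.663 times (0.0145). These expected numbers follow gene counts, while 573 of the 778 common peaks lay over 5000 bp from a TSS. Expected numbers from chromosome length were not computed. The chromosome 1 call was lost whichever replicate was left out (adjusted exact p = 0.157 to 0.363), the chromosome 2 call without replicate 2 (0.227) and the chromosome 7 call without replicate 1 (0.0935) and without satellite, rRNA and snRNA repeat peaks (0.147).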

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

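Leaving out satellite, rRNA and snRNA repeat peaks or 3 LTR families, matching on current symbols alone and counting peaks of a class within 50 kb, or also those with repeated scores, as 1 were chosen only after the results were seen. Over all settings, 432 recomputed values of the main results were kept, 24 moved, 9 calls were lost, 3 were gained and 0 reversed. A tested value was kept if its direction and side of the threshold held, and the promoter share if it stayed within its main interval. A count was kept if the larger value was at most 50% above the smaller. Of the values of single chromosomes and annotation classes, 124 kept their call, 12 calls were lost and 7 gained. The lost class call was that of satellite peaks in all 3 lists, with peaks within 50 kb counted as 1, with or without repeated scores (adjusted exact p = 1 over 4 regions in both). The histone list passed in all settings, with adjusted p between 5.95e-62 and 6.48e-05, the latter as loci, a setting that favours clustered lists by construction. The cause of the changes below was not tested except where the setting keeps fewer peaks or lists by construction. Peaks at or above each list's median score numbered 1485, 1307 and 1371 in the 3 replicates, by construction, and 501 common peaks were then in at least 2 lists. A 50% reciprocal overlap left 157 peaks shared by all 3 replicates and 155 common peaks in all 3 lists. With a replicate left out, peaks shared by the remaining lists numbered 402 to 443 and common peaks in both of them 391 to 435, since fewer lists had to be matched. The promoter share was 18.9% for peaks in all 3 lists, 14.4% and 26.35% within 500 and 5000 bp of a TSS, and 13.6 to 14.3% with a replicate left out. The olfactory receptor call was lost within 1000 bp (adjusted exact p = 0.0569), with all annotated genes as background (0.181), as loci (1), for peaks in all 3 lists (0.190) and with a replicate left out (0.0577 to 0.0763). The splicing call was lost for peaks in all 3 lists (0.1098) and without replicate 3 (0.168; 0.0307 to 0.168 over the replicates left out), and the lists past the threshold then numbered 2 and 2 (2 to 3 over the replicates left out). With all annotated genes as background, other histone modifiers (0.0348) and Zfp genes (0.00237) passed, and Zfp genes also as loci (0.0422), whereas Zfp genes matched on current symbols alone had 0.643. The chromosomes past the threshold numbered 8 with expectations from protein-coding genes, 3 without the repeat peaks and 3 to 5 with a replicate left out. Chromosome X gained a deficit without replicate 1 (6 peaks against 19.67 expected, exact binomial test, adjusted p = 0.00481) and without replicate 3 (6 against 21.02, 0.00194). It did not without replicate 2 (19 against 21.88, 0.815). No paired analysis was possible because the input is a single sample and only the ChIP group has replicate numbers. The motif search and the comparison of TSS distances with random positions were not run, since the mm9 sequence and annotation were not used here. The unknown read depth limits what the absence of a weak peak from a list can show.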

Other observations

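The tests of ribosomal protein genes, of random gene runs, of equal-score peaks and of the kinds of peaks missing from replicate 2 were chosen only after the results they bear on were seen. The genes in this paragraph were chosen after their values were seen and lie outside the naming rule. The strongest promoter peak outside the regions described was at Nrarp, a target and feedback inhibitor of Notch signalling, on chromosome 2 from 25035801 to 25036694, 31 bp upstream of the TSS, with scores of 689, 757 and 786 in replicates 1, 2 and 3. Nrarp was not a member of the fixed Notch list. Rnu11, the gene of the U11 snRNA of the minor spliceosome, had a peak 7 bp upstream of its TSS (539, 558 and 397). Slc39a10, a zinc importer, had one 129 bp upstream (629, 285 and 384), and Jund, an AP-1 subunit, one in the 5′ UTR (294, 349 and 268). Promoter peaks in all 3 lists also lay at Gpr137 (318, 259 and 178), at Esrra, an orphan nuclear receptor of mitochondrial biogenesis (101, 197 and 172), at Hmgb1, an abundant chromatin protein (63.2, 238 and 186), and at Eif4g2, a translation factor (207, 106 and 69.8).

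Foxo1, Ddit4, Pecam1 and Lhcgr also lie outside the naming rule, and the genes and repeats described here were chosen after their values were seen. Counting common peaks at any distance from the TSS, 2 of 25 genes of the stem spermatogonia list, 1 of 10 endothelial genes and 1 of 12 Leydig cell genes had a peak, which was not told apart from the 2.51% of other genes (adjusted exact p = 0.625 to 0.8145). Foxo1, of the stem spermatogonia list and a regulator of spermatogonial stem cells, had an intergenic peak 12720 bp upstream of its TSS on chromosome 3 from 52059271 to 52059807 (scores 161 and 163 in replicates 1 and 2, none in replicate 3). Ddit4, of the same list, had a peak 35944 bp downstream (75.97, 49.6 and 42.1). Of the somatic lists, the endothelial gene Pecam1 had a peak in a U3 repeat 10023 bp upstream (162, 103 and 165), and the Leydig cell gene Lhcgr an intronic peak 16602 bp downstream (48.6 and 55.5 in replicates 1 and 2, none in replicate 3). Among the other histone modifiers, Setd2, a histone H3 lysine methyltransferase, had a peak 6083 bp upstream in a SINE (211, 170 and 117). In LTR retrotransposons, 6 RLTR13A3 and 7 RLTR10 peaks were all missing from replicate 2, and 6 RLTR1B peaks were all missing from replicate 1. These peaks largely carried 1 repeated score and so are not separate absences: in replicate 1, 5 of the 7 RLTR10 peaks scored 58.2 and 5 of the 6 RLTR13A3 peaks 74.9, and in replicate 2, 4 of the 6 RLTR1B peaks scored 41.6.

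Binding at replication-dependent histone genes could be a general property of highly expressed loci, of clustered genes or of repeated gene copies. Ribosomal protein genes, which growing cells express highly, had 1 of 91 bound, Ubb by a synonym, against 32 of 67 histone genes (Fisher's exact test, two-sided, p = 1.09e-13). This argues against a peak at every highly expressed gene. Expression was not measured here and only 1 gene family was compared, so a part for high expression stays open. Histone loci held a bound gene in 3 of 5 cases, against a mean of 0.333 for random runs of as many neighbouring genes (one-sided permutation p = 0.00137), which argues against repeated counting of neighbours as the whole cause. Reads shared between near-identical histone gene copies stay open: 6 of the 38 histone peaks, at Hist2h3c2, Hist1h2br and Hist1h2ao, overlapped a replicate peak with an equal-score, equal-width partner within 100 kb, but reads placed at random among copies would leave no such pairs. Pairs of peaks at Hist2h2aa1, Hist2h3c1 and Hist1h4n also carried 1 gene name at separate places, without such a partner. Features of histone genes other than expression, such as their open chromatin in S phase, also stay open without input values, and no biological explanation was tested because the design has no ChIP group lacking SOX3.

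The very high scores in snRNA repeats may come from reads shared between near-identical copies. Among the 622 peaks with a score of 100 or more in the 3 lists, 8 pairs within 100 kb had equal score and equal width, against at most 1 in 1000 shuffles of the scores, so reads shared between near-identical copies are a candidate explanation for those pairs. Their nearest genes, looked up after the values were seen, were Hist2h3c2, Terc, Eapp, BC107364, 9030025P20Rik with Gm3448, and Gm10057 with Gm16445. Of the 36 snRNA common peaks, however, 2 had such a partner at any score. For most of them shared reads, binding and background cannot be told apart from these lists, since no input values were analysed here. No biological explanation was tested.

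Satellite peaks were nearly confined to replicates 1 and 3, with 20 of 21 (95.2%) missing from replicate 2, against 182 of 757 other common peaks (24.0%), but they lay in only 4 regions, 3 of them missing from replicate 2. Outside satellites, with peaks within 50 kb or of repeated scores counted as 1, 69 of 215 units in repeats (32.1%) and 65 of 380 outside repeats (17.1%) were missing from replicate 2 (Fisher's exact test, two-sided, p = 3.98e-05). However, 17.2% of the units in repeats and 37.6% of those outside were in all 3 lists, and every other unit must be missing from a list. The difference is thus partly built in and does not decide whether replicate 2 lacked peaks of every kind alike. Counted the same way, 10 of 14 rRNA units (71.4%) were missing from it, against 21.5% of the others (exact p = 0.000117), whereas LINE L1 units were not told apart from the others (29.3% against 21.7%, exact p = 0.142). With only peaks within 50 kb counted as 1, 35.5% of LINE L1 regions were missing from replicate 2, against 22.7% (exact p = 0.0126). The LINE L1 result thus depended on the setting, and it carries the same built-in part. The satellite peaks missing from replicate 2 had a median best score 1.54 above that of other peaks missing from it (permutation p = 0.789), so a place just under the score limit could neither be shown nor excluded. A difference between libraries in the yield or removal of highly repeated DNA stays open, as does a difference between testes, which the design does not separate from the library.

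The hypothesis that strong intronic peaks outside annotated repeats mark genes hosting a small nuclear or small nucleolar RNA gene was tested on 166 peaks. The host held such a gene for 7 of 83 stronger and 3 of 83 weaker peaks (odds ratio 2.46, Fisher's exact test, two-sided, p = 0.329), so these data do not decide it.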
